A study of Caenorhabditis elegans with 12 samples.

How the data were processed

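The deposited files hold 1 library each, 12 in all, from whole day 1 adult animals of 4 genotypes with 3 libraries per genotype. Per the file headers, the deposited values are expected counts per gene, not scaled to depth. The authors' notes name HISAT2 2.0.5, StringTie 1.3.3, RSEM 1.3.1, limma 3.24.15 and R 3.1.3 and the builds ce11 and WBcel235, without saying which tool did which step. Each file lists 46904 gene IDs, of which 44017 carry a symbol; 46817 were found in the WBcel235 annotation (Ensembl release 115), which gave positions and exon lengths. In each library 1.678% to 2.991% of values were not whole, and total counts ran from 19394046 to 41009125.

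The genotype of each library was taken from its label. The protocol states 3 biological repeats, the last sequenced as a later set, and does not say which number that was; all libraries were taken as given by genotype. The growth protocol has animals moved at the L4 stage to plates with control or pfd-6 RNA interference bacteria, and the series design text speaks of daf-2 animals on control or hsf-1 RNA interference. No label says which plates a library came from, so a treatment that differed between libraries would change what the genotype contrasts mean. No 2 libraries of a genotype agreed within sampling noise (lowest chi-square per degree of freedom 22.38). Replicates 1 and 2 were closest in every genotype, at 103.6 in N2, 169.3 in daf-2, 426.5 in pfd-6 and 22.38 in the double mutant. Pairs with replicate 3 gave at least 220.9, 565.8, 772.5 and 68.46. Replicate numbers were checked for pairing by correlating deviations from the genotype means for same-numbered libraries. Every pair exceeded 0.1 for N2 with daf-2 (0.453, 0.271 and 0.31) and for daf-2 with the double mutant (0.315, 0.211 and 0.137), so values blocked on the replicate number stand beside those comparisons. For N2 with pfd-6 (0.345, 0.034 and 0) and pfd-6 with the double mutant (0.299, 0.049 and 0.019) they did not. The pairs not compared directly also exceeded it: daf-2 with pfd-6 (0.749, 0.655 and 0.704) and N2 with the double mutant (0.33, 0.368 and 0.501).

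Expected counts were rounded to whole numbers, filtered with filterByExpr (15090 genes kept) and scaled by TMM. Quasi-likelihood models in edgeR 4.0.16 (R 4.3.3) were fitted to all 12 libraries with genotype as the covariate. The 4 pairwise contrasts and the interaction, the daf-2 effect in the pfd-6 background minus that in the wild-type background, were tested, with a threshold of 0.05 on Benjamini-Hochberg adjusted p. CPM are TMM-scaled. A fold against a group with 0 counts is given as a lower bound against 3 counts over that group. The entries of 73 genes held identical values in all libraries and cannot be told apart.

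The 26 gene lists were fixed before the data were examined: DAF-16 targets (raised and lowered classes), insulin/FOXO pathway, prefoldin, TRiC/CCT chaperonin, tubulin and actin, heat shock proteins, ER stress, mitochondrial stress, detoxification, innate immunity, vitellogenins, fat metabolism, sugar and glyoxylate metabolism, autophagy and lysosome, proteasome, cytosolic ribosomal proteins, cuticle collagens, molting cycle, germline and oocyte, sperm, embryo, muscle, pharynx, neuron and intestine. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and with an estimated correlation, adjusted over 130 tests. At the preset correlation 62 tests passed and with an estimated correlation 0; the lowest adjusted p was then 0.599.

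Named genes were, for daf-2 vs N2, pfd-6 vs N2 and the double mutant vs daf-2, the 10 steepest rises and 10 steepest falls among genes past the threshold with at least 10 CPM in the higher group and no overlap between the libraries of the groups, a separation that 10% of splits give by chance; for the other contrasts 5 and 5, with no overlap rule for the interaction. pfd-6, daf-2, daf-16 and hsf-1 and up to 4 members of each list with the smallest p were added.

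The share of the daf-2 response kept in the pfd-6 background was measured in 1 replicate number on genes chosen from the others, as the ratio of median signed log2 differences. Alternatives were DESeq2 1.42.0, RLE size factors, limma-voom, no filter, a stricter threshold, the compared groups alone, the replicate number as a block, replicates 1 and 2 alone and each library left out. Settings added after the data were seen were a transcript length offset (a spline with 5 degrees of freedom per library), with and without the block, and leaving out daf-2 replicate 3 and pfd-6 replicate 3 or the genes of a chromosome V stretch. Tested on simulated data, the model called 1.64% of genes changed 2-fold, 25% of those changed 4-fold and 67.2% of those changed 8-fold for daf-2 vs N2, and 0%, 5.56% and 18.4% for the interaction. GC content was not analysed here.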

Results

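Whole Caenorhabditis elegans animals at day 1 of adulthood were profiled by paired-end mRNA sequencing in 12 libraries, 3 of each of 4 genotypes. The genotypes were the N2 wild type, daf-2(e1370), with a mutation in the insulin/IGF-1 receptor gene, pfd-6(gk493446), with a mutation in a gene for a prefoldin subunit, and the pfd-6;daf-2 double mutant. Total expected counts in replicates 1, 2 and 3 were 41009125, 37571267 and 19394046 for N2, 27500825, 32029679 and 23646949 for daf-2, 31353315, 31048168 and 22854344 for pfd-6, and 29232173, 32374704 and 22295483 for the double mutant. At this depth 3 counts over the N2 group, the floor used for fold changes, came to 0.036 CPM (counts scaled by library size and TMM). Transcripts of pfd-6 (WBGene00009004; chromosome I, 7282964 to 7283762) averaged 111 ± 28.9 CPM in N2, 101 ± 50.1 in daf-2, 13.9 ± 6.53 in pfd-6 and 15.9 ± 1.32 in the double mutant (SD, n = 3 each).

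Ribosomal protein genes took 1.41% of the counts in daf-2 replicate 3 (95% Wilson interval 1.401 to 1.41) and 0.609% in pfd-6 replicate 3 (0.6056 to 0.6119), against 9.33% to 15.9% in the other 10 libraries. These intervals cover counting error only. In N2, a stretch of chromosome V (WBcel235, 17339084 to 17551209) held 9 counts where the rate in the other 9 libraries predicted 5563. Both features were noticed in the data.

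The comparison of daf-2 with N2 asks which transcripts change when insulin/IGF-1 signalling is reduced. Transcripts of sod-3, a manganese superoxide dismutase, rose from 7.57 ± 1.4 CPM in N2 to 39.2 ± 14.6 in daf-2 (log2 fold change 2.37, SE 0.32, adjusted p = 0.00387; SD, n = 3). The metallothionein transcript mtl-1 rose from 2.22 ± 0.935 to 47.5 ± 30.5 CPM (log2 fold change 4.40). Changes were ranked among called genes of at least 10 CPM in the higher group with no overlap between libraries. By this ranking the steepest rise outside the chromosome V stretch was in H39E23.3 (WBGene00044201, chromosome V, 14107811 to 14110051), from 0.639 ± 0.32 to 274 ± 68.1 CPM (log2 fold change 8.67, SE 0.83). The invertebrate-type lysozyme transcript ilys-5 (WBGene00017691, chromosome X, 6533490 to 6536840) showed the steepest fall by the same ranking, from 454 ± 211 to 0.648 ± 0.184 CPM (log2 fold change -9.44, SE 0.96, adjusted p = 0.00043). In all, 141 of 15090 tested genes passed the edgeR test, 108 higher and 33 lower in daf-2, each with at least a 2-fold change.

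Other steep rises were in icmt-1 (log2 fold change 7.47), which encodes an isoprenylcysteine carboxyl methyltransferase, Y39G8B.7 (7.24), clec-15 (6.83), F15B9.6 (5.80), Y9C9A.16 (5.04), F17B5.1 (4.48) and unc-38 (4.31), a nicotinic acetylcholine receptor subunit. The neighbouring genes icmt-1 and unc-38 on chromosome I were highest in daf-2 replicate 3, at 99.2 and 73.3 CPM, against 4.6 and 12.5 CPM in replicate 1. The C-type lectin transcript clec-10 fell by 7.94 on the log2 scale, from 14.4 ± 1.45 to 0.0538 ± 0.0173 CPM. Further falls were in dod-24 (-4.39), nspc-16 (-4.02), F55G11.2 (-3.97), clec-190 (-3.40), nspc-13 (-3.02), C32H11.4 (-2.67), the saposin-like spp-4 (-2.24) and the acyl-CoA oxidase acox-1.2 (-2.08). The gene lsy-27 (WBGene00009834) had 0 counts in N2 and 20.1 ± 10.8 CPM in daf-2, at least 556-fold higher, and it is 1 of 16 genes called higher in daf-2 that lie in the chromosome V stretch.

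By list, 4 of 24 tested members of the raised class of DAF-16 targets passed (10 when adjusted over the list alone): sod-3, mtl-1, the transhydrogenase nnt-1 (2.04) and the cytochrome P450 cyp-35B1 (2.29). The list's median log2 fold change was 0.73, with adjusted p = 1.42e-05 by limma camera at a preset correlation, and adjusted p = 0.599 with an estimated correlation. Of 12 members of the lowered class, dod-22 (-4.07) and dod-24 (-4.39) fell and the other 10 did not pass. In the innate immunity list of 42, ilys-5 and F55G11.2 fell while the saposin-like spp-9 rose (7.47). Among 33 detoxification genes the UDP-glucuronosyltransferase ugt-13 rose (1.96), and among 36 fat metabolism genes the lysosomal lipase lipl-1 rose (2.37). No member of the other lists passed. Their medians were -1.24 for the 6 vitellogenins, -0.54 for the TRiC/CCT chaperonin, -0.17 for prefoldin and for heat shock proteins, -0.38 for tubulin and actin, -0.69 for ribosomal proteins and -1.52 for sperm genes. They were -0.66 for collagens, 0.21 for molting, -0.56 for germline and oocyte, 0.40 for embryo, -0.51 for muscle, -0.73 for pharynx, 0.14 for neuron and -0.32 for intestine. They were -0.09 for the insulin/FOXO pathway, -0.19 for ER stress, -0.085 for mitochondrial stress, -0.33 for sugar and glyoxylate metabolism, 0.04 for autophagy and lysosome and -0.38 for the proteasome. Several of these medians depend on replicate 3. Without daf-2 replicate 3 and pfd-6 replicate 3 they were -0.16 for ribosomal proteins, -1.01 for sperm, -0.31 for collagens (3 higher, 1 lower), -0.41 for molting and 0.09 for heat shock proteins. With replicates 1 and 2 alone they were 0.12 for sperm and 0.50 for collagens (9 higher, 1 lower). The same setting gave 0.007 for sugar and glyoxylate metabolism, 0.05 for mitochondrial stress, -0.12 for autophagy and lysosome, -0.14 for the proteasome and -0.16 for muscle. Vitellogenins (-0.99) and embryo (0.41) moved less. With the replicate number as a block, the ribosomal protein median was -1.37, 1 embryo gene was higher and 2 fat metabolism genes were lower. Adjusted over each list alone, 5 detoxification genes and 1 embryo gene were higher, and 3 innate immunity genes, 1 fat metabolism gene and 1 muscle gene were lower.

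Leaving out 1 library gave 41 genes without N2 replicate 1, 45 without N2 replicate 2, 84 without N2 replicate 3, 69 without daf-2 replicate 1, 66 without daf-2 replicate 2 and 249 without pfd-6 replicate 3, which shares the fit. The count was 253 (182 higher, 71 lower) with the replicate number as a block, 401 with DESeq2, 49 at an adjusted p under 0.01, 222 without daf-2 replicate 3 and pfd-6 replicate 3, and 107 (80 higher, 27 lower) without the genes of the chromosome V stretch.

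**Figure D1:**
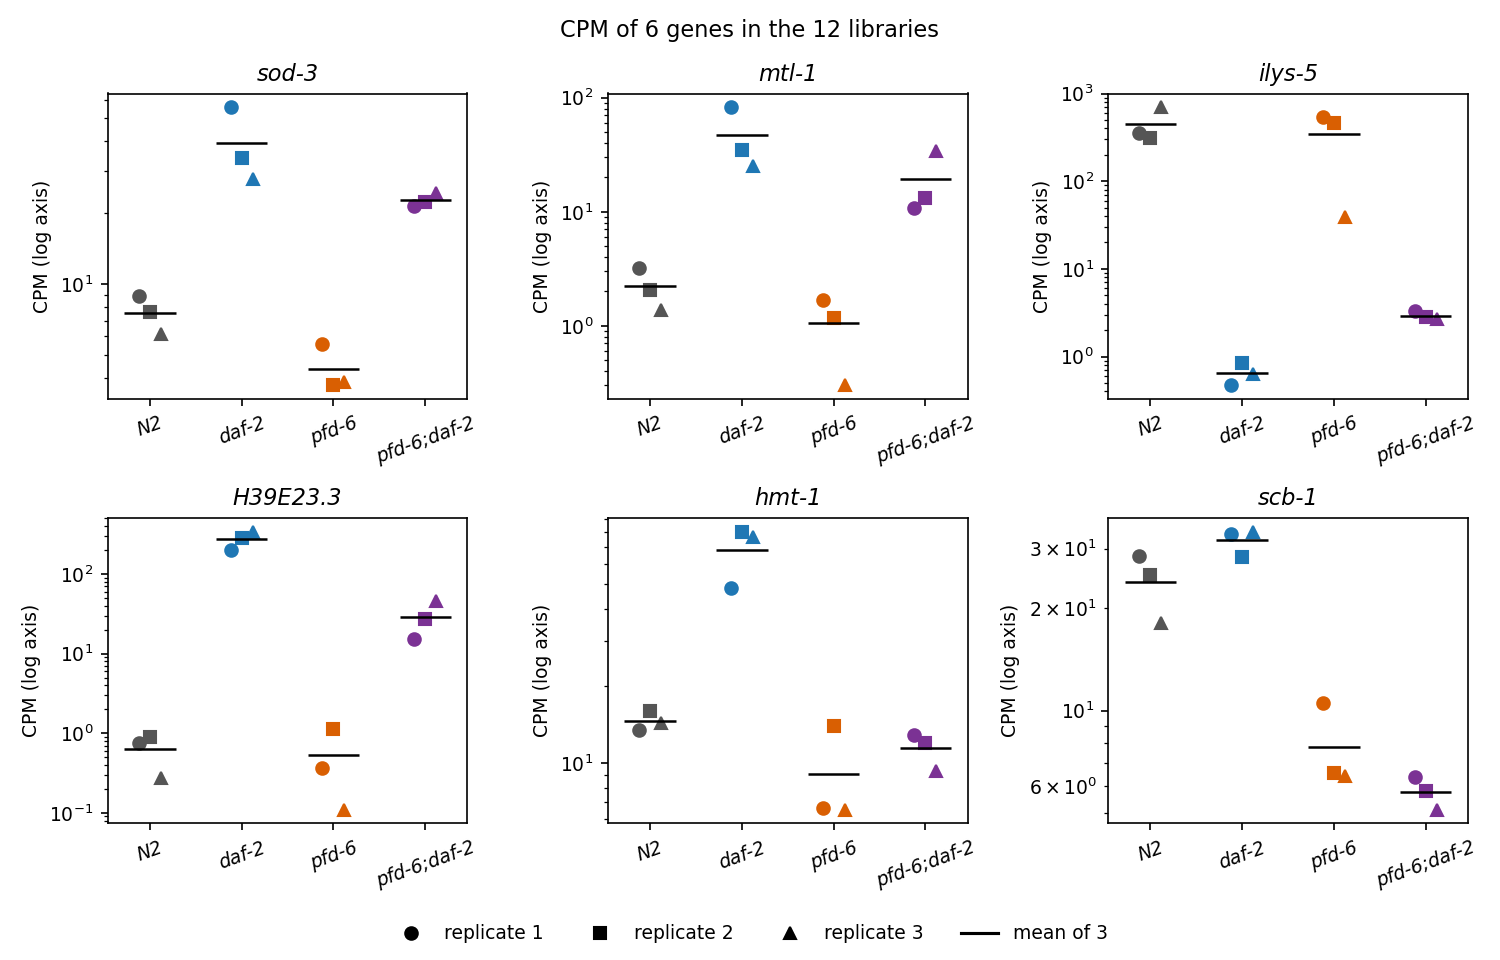
CPM on a log axis for sod-3, mtl-1, ilys-5, H39E23.3, hmt-1 and scb-1 in the 12 libraries. Symbols mark replicates and bars the group mean of 3; H39E23.3 averaged 274 CPM in daf-2 and 29.2 in the double mutant, and scb-1 averaged 31.7 and 5.76.

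The comparison of the double mutant with daf-2 asks how loss of pfd-6 changes the transcripts of animals with reduced insulin/IGF-1 signalling. Sperm transcripts were higher in the double mutant: 37 of 61 tested members of the sperm list passed (54 when adjusted over the list alone), with a median log2 fold change of 4.495. The major sperm protein transcripts msp-59, msp-53 and msp-79 rose by 4.56, 4.63 and 5.55 on the log2 scale, and msp-59 went from 1.33 ± 0.527 to 31.4 ± 16 CPM. The sperm phosphatase transcript gsp-4 rose by 4.36 and ssp-35 by 4.71 on the log2 scale. Cuticle collagens were also higher, with 25 of 137 tested members passing (66 when adjusted over the list alone) and a median of 2.15; col-156 (7.22), col-88 (6.44), col-138 (5.09), col-161 (5.02), col-90 (4.58), col-120 (4.05) and col-38 (2.72) were among them. In all, 470 genes passed, 412 higher and 58 lower in the double mutant.

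The list tests at a preset correlation gave adjusted p = 1.16e-43 for sperm and adjusted p = 4.68e-32 for collagens, and adjusted p = 0.599 for each with an estimated correlation. Without daf-2 replicate 3 and pfd-6 replicate 3, 4 sperm genes (median 4.02) and 7 collagens (median 1.81) passed. The geometric mean CPM of the sperm list was 6.194, 4.908 and 11.26 in the double mutant libraries, between 0.2219 and 0.8763 in daf-2, and 0.7168, 0.6148 and 2.404 in N2 replicates 1, 2 and 3.

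Other steep rises in the double mutant over daf-2 were in Y47D7A.15 (6.74), ZK180.5 (6.03), F17E9.5 (5.30), nsph-4.1 (5.27), msp-10 (5.18) and grl-16 (5.06). Among called genes of at least 10 CPM in daf-2 with no overlap between libraries, falls were led by F17E9.2 (16-fold lower), clec-222 (-3.70) and H39E23.3 (-3.23). Next came pfd-6 itself (-2.66, adjusted p = 0.0162) and hmt-1 (-2.59), which encodes an ABC transporter of heavy metal tolerance. F59A6.12 (-2.55), scb-1 (-2.46), Y106G6H.16 (-2.41), hsr-9 (-2.24) and T23F11.6 (-2.16) were also lower. The scb-1 transcript (WBGene00010407; chromosome V, 11118766 to 11119705) went from 31.7 ± 2.87 CPM in daf-2 to 5.76 ± 0.637 (SE of the log2 fold change 0.30, adjusted p = 0.0123). In the innate immunity list F55G11.2 was higher (2.56), the single such member.

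None of the 24 tested members of the raised class of DAF-16 targets passed between the double mutant and daf-2, and their median log2 fold change was 0.08. Without daf-2 replicate 3 and pfd-6 replicate 3, 1 member was higher and the median was 0.07. The sod-3 transcript averaged 22.6 ± 1.35 CPM in the double mutant (log2 fold change -0.79, SE 0.31, adjusted p = 0.235) and mtl-1 averaged 19.4 ± 12.7 CPM (-1.30, SE 0.63, adjusted p = 0.364). No heat shock protein passed (22 tested, median -0.32), nor did any muscle gene (23 tested, median 0.96) or pharynx gene (15 tested, median 1.425). Fold changes were positive for all 23 muscle and all 15 pharynx genes. Camera gave adjusted p = 1.14e-06 and 0.000191 at a preset correlation, and 0.679 for each with an estimated correlation. All 7 prefoldin genes had negative fold changes (median -0.53), and pfd-6 alone passed. Their adjusted p by camera was 0.0107 at a preset and 0.599 with an estimated correlation. Replicates 1 and 2 alone gave 1 lower heat shock gene. With the replicate number as a block 3 muscle genes, 1 pharynx gene, 1 intestine gene and 1 fat metabolism gene were higher. In the same fit 1 gene each was lower in the lists of tubulin and actin, detoxification, collagens and the lowered class of DAF-16 targets. Adjusted over each list alone, 2 innate immunity genes were higher, and 1 gene each was lower in the lists of tubulin and actin and of collagens. Transcripts of daf-2, daf-16 and hsf-1 did not pass in any of the 5 comparisons.

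The count of 470 rested on each library: it was 0 without daf-2 replicate 1, 12 without daf-2 replicate 2, 0 without daf-2 replicate 3, and 24, 222 and 6 without double mutant replicates 1, 2 and 3. It was 311 without N2 replicate 2 and 714 without pfd-6 replicate 3, while 2265 genes had an unadjusted p under 0.05 and DESeq2 called 916. It was 814 (623 higher, 191 lower) with the replicate number as a block, 2 at an adjusted p under 0.01, 145 with replicates 1 and 2 alone, 163 without daf-2 replicate 3 and pfd-6 replicate 3, and 587 (438 higher, 149 lower) with a transcript length offset.

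**Figure D2:**
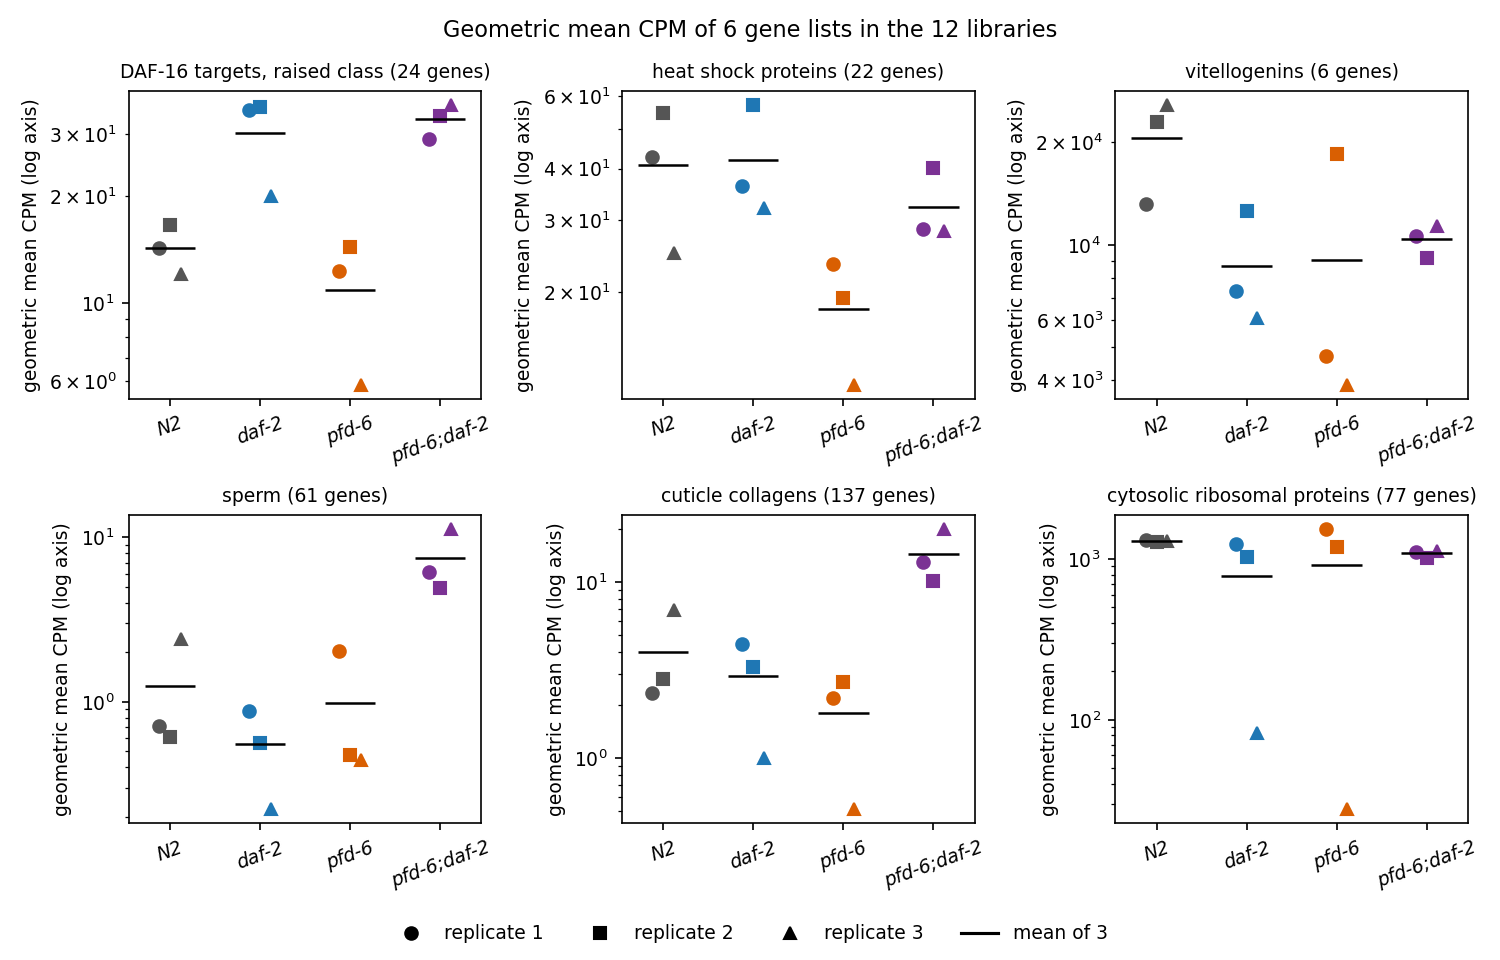
Geometric mean CPM on a log axis of 6 gene lists in the 12 libraries, with symbols for replicates and bars for the mean of 3. The sperm list lies between 4.908 and 11.26 CPM in the double mutant and at most 2.404 elsewhere; ribosomal proteins drop to 82.53 in daf-2 replicate 3 and 27.7 in pfd-6 replicate 3.

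The comparison of pfd-6 with N2 asks what the pfd-6 mutation changes where daf-2 is intact. The pfd-6 transcript fell by 2.99 on the log2 scale (SE 0.42, adjusted p = 0.0116) and was the lone gene lower by this test. The pfd-6 call was lost without N2 replicate 1 (log2 fold change -2.71, adjusted p = 0.0848), without pfd-6 replicate 2 (-2.87, adjusted p = 0.0956), without pfd-6 replicate 3 (-2.73, adjusted p = 0.0826) and without daf-2 replicate 3 and pfd-6 replicate 3 together (-2.69, adjusted p = 0.0834). It was also lost with replicates 1 and 2 alone (-2.79), with the compared groups alone (-2.98) and without the genes of the stretch (-2.99, adjusted p = 0.0809). Of the 14 genes higher in pfd-6, 13 lay in the chromosome V stretch with almost no N2 counts. They included lsy-27, with 0 counts in N2 and 18.5 ± 11.9 CPM in pfd-6 (at least 481-fold higher), and fbxb-7, an F-box gene (at least 214-fold). The remaining gene, ins-19, an insulin-like peptide gene named after its values were seen, averaged 0.00868 CPM in N2 and 3.36 in pfd-6. None of the heat shock protein genes passed (22 tested, median -1.09; 1 was lower when adjusted over the list alone), with hsp-70 at 4.09 ± 3.84 CPM in N2 and 0.292 ± 0.144 in pfd-6 (log2 fold change -3.80, adjusted p = 0.614). The heat shock list had adjusted p = 2.61e-04 at a preset correlation and adjusted p = 0.599 with an estimated correlation. Its median was -0.95 without daf-2 replicate 3 and pfd-6 replicate 3, and -0.385 with replicates 1 and 2 alone. The raised class of DAF-16 targets had a median of -0.35 and no member past the test, with adjusted p = 0.00687 at a preset and adjusted p = 0.679 with an estimated correlation. Without daf-2 replicate 3 and pfd-6 replicate 3 its median was -0.38 and 1 member was higher. Camera at the preset correlation then gave adjusted p = 0.115.

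Beyond pfd-6, no list held a gene that passed between pfd-6 and N2. Adjusted over the list alone, 1 collagen was lower. List medians in this comparison were negative except in the lowered class of DAF-16 targets (0.02), prefoldin (0.12) and embryo (0.25), but many moved toward 0 or turned in sign without replicate 3. Medians were -1.19 for vitellogenins, -1.045 for pharynx, -0.69 for molting, -0.67 for sugar and glyoxylate metabolism, -0.76 for the TRiC/CCT chaperonin, -0.86 for tubulin and actin, and -1.14 for cuticle collagens. Without daf-2 replicate 3 and pfd-6 replicate 3 these 7 were -0.84, -1.33, -0.79, -0.40, -0.54, -0.52 and -0.645, and with replicates 1 and 2 alone -0.65, -0.84, -0.04, -0.14, -0.23, -0.38 and -0.10. Medians were -0.52 for ER stress, -0.53 for germline and oocyte, -0.41 for muscle and -0.53 for intestine, and with replicates 1 and 2 alone -0.16, -0.07, -0.14 and -0.29. Without daf-2 replicate 3 and pfd-6 replicate 3 the sign turned for ribosomal proteins (-0.45 to 0.15), sperm (-0.25 to 0.19), innate immunity (-0.23 to 0.12), mitochondrial stress (-0.15 to 0.02) and the lowered class (to -0.03). With replicates 1 and 2 alone it turned for ribosomal proteins (to 0.075), sperm (to 1.24), the proteasome (-0.375 to 0.05), detoxification (-0.125 to 0.06), fat metabolism (-0.25 to 0.003), the lowered class (to -0.34) and embryo (to -0.04). A transcript length offset turned it for autophagy and lysosome (-0.30 to 0.02) and neuron (-0.02 to 0.095). The count of 15 genes was 9 without N2 replicate 1 and 31 with DESeq2. When the genes of the chromosome V stretch were left out, edgeR called 0 genes and pfd-6 no longer passed; in the full set 1045 genes had an unadjusted p under 0.05.

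**Figure D3:**
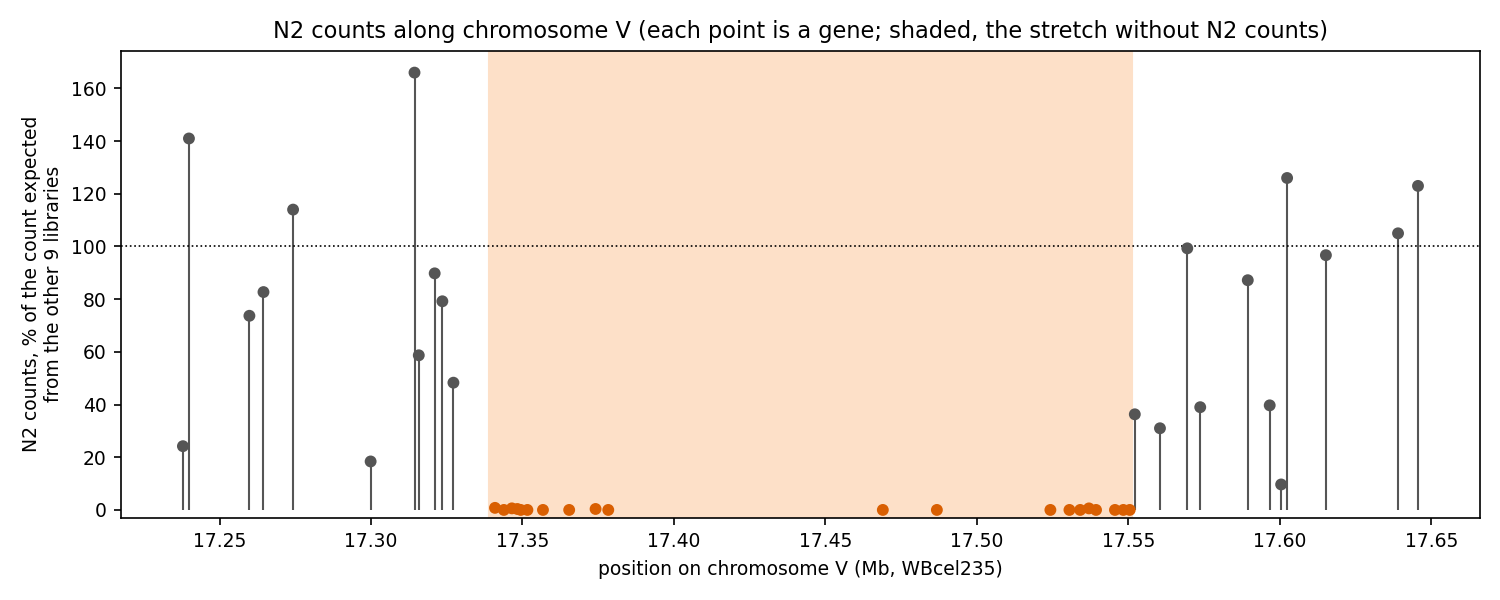
N2 counts of genes along chromosome V (WBcel235, position in Mb), as a percent of the count expected from the other 9 libraries; each point is a gene and the shaded band is the stretch. The 20 genes inside lie under 1%, and the 22 genes within 100 kb outside have a median of 81%.

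The comparison of the double mutant with pfd-6 asks which transcripts respond to the daf-2 mutation where pfd-6 is also mutated. Transcripts of sod-3 rose by 2.36 (SE 0.32, adjusted p = 0.00435) and those of mtl-1 by 4.20 on the log2 scale. Of the 24 members of the raised class of DAF-16 targets, 6 passed (9 when adjusted over the list alone), nnt-1 (2.02) and lea-1 (2.86) among them, and the median was 1.23. The list had adjusted p = 7.51e-09 at a preset correlation and adjusted p = 0.599 with an estimated correlation. Of the lowered class dod-22 (-4.76) and dod-24 (-3.68) fell. Among genes of at least 10 CPM the steepest fall was again in ilys-5, by 6.87 on the log2 scale, followed by the antimicrobial peptide gene cnc-2 (-5.40), dod-22, pud-1.1 (-4.04) and clec-190 (18.8 ± 8.14 CPM in pfd-6, 1.16 ± 0.395 in the double mutant). Steep rises were in clec-18 (10.46), F35E8.6 (10.32), Y39G8B.7 (9.68) and spp-9 (8.92). Over the alternative settings these ran from 7.09 to 12.27, 6.36 to 12.08, 8.72 to 10.04 and 6.39 to 9.41. F35E8.7 had 0 counts in pfd-6 and was at least 464-fold higher in the double mutant, with means of 1.52 ± 0.269 CPM in daf-2 and 18.9 ± 30.6 in the double mutant. In all, 497 genes passed, 346 higher and 151 lower.

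Cuticle collagens made up 52 of the higher genes (137 tested, median 3.155; 81 when adjusted over the list alone), with col-156 (7.27), col-62 (5.37), col-147 (5.05) and col-38 (4.13). Sperm genes made up 10 (61 tested, median 3.235; 53 when adjusted over the list alone), with gsp-4 (3.89), msp-59 (3.18), ssp-10 (2.79) and smz-1, which went from 1.4 ± 1.1 to 11.3 ± 2.46 CPM. The sperm count was 1 (63 tested, median 2.745) without daf-2 replicate 3 and pfd-6 replicate 3. It was 5 with replicates 1 and 2 alone and 29 with a transcript length offset. The geometric mean CPM of the collagen list was 2.2, 2.709 and 0.5097 in pfd-6 replicates 1, 2 and 3. In the double mutant it was 12.95, 10.17 and 20.05. Of the 346 higher genes, 125 were also higher in the double mutant over daf-2, which rests on the same double mutant libraries. A difference of age or stage in those cultures would enter both comparisons. The list tests gave adjusted p = 4.34e-33 for collagens and adjusted p = 2.27e-25 for sperm at a preset correlation, and adjusted p = 0.599 for each with an estimated correlation. Single members passed in the heat shock list (hsp-70, 4.02), the pharynx list (abu-13, 2.36), the neuron list (the neuropeptide gene flp-1, 1.79) and the insulin/FOXO list (the insulin-like peptide gene ins-7, -4.47). In the molting list mlt-9 (2.42) and wrt-4 (2.80) were higher.

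Of the 42 innate immunity genes 4 were higher and 4 lower, with clec-4 (3.06), clec-60 (4.09), spp-9 and ilys-5 at the smallest p. Of the 33 detoxification genes ugt-13 was higher (1.92) and the cytochrome P450 genes cyp-35C1 (-2.43), cyp-35A5 (-2.38) and cyp-35A2 (-2.16) were lower. Of the 36 fat metabolism genes hacd-1 (2.02) and lipl-1 (1.91) were higher and acdh-2 (-3.95) and lbp-7 (-1.59) lower. Adjusted over each list alone, 6 innate immunity genes were higher and 6 lower, 3 fat metabolism genes higher and 4 lower, 7 pharynx and 3 molting genes higher, and 4 of the lowered class of DAF-16 targets lower. The count of 497 was 187 without pfd-6 replicate 1, 803 without pfd-6 replicate 2, 301 without N2 replicate 2, and 126, 161 and 123 without double mutant replicates 1, 2 and 3. It was 64 at an adjusted p under 0.01, 1290 with DESeq2, 248 from the compared groups alone, and 1137 (444 higher, 693 lower) with a transcript length offset, where higher genes are the minority.

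The daf-2 response was then compared between the pfd-6 backgrounds. Across all tested genes, which are not independent replicates, the Spearman correlation of the daf-2 effects was -0.143, and -0.224 on group means of log2 CPM. Differences between replicate numbers, which hold no genotype effect, gave -0.433, -0.584 and -0.663 on the latter scale. The correlation over all genes therefore shows neither a shared nor an opposed daf-2 response. Called genes were compared separately. Of 125 genes outside the chromosome V stretch that passed between daf-2 and N2, 121 had the same sign between the double mutant and pfd-6. The 92 raised genes had a median log2 fold change of 3.20 in the wild-type background, in which they were chosen, and 1.92 in the pfd-6 background, and the 33 lowered genes had -3.40 and -3.12. Choosing genes in some libraries and measuring them in others removes the part of the choosing background's advantage that comes from noise. All genes were still chosen on daf-2 vs N2, so genes with a larger response in the wild-type background were favoured. With genes chosen from replicates 1 and 2 and measured in replicate 3, the 198 genes kept a share of 0.863 of their response; leaving out replicate 1 or 2 gave 0 genes to measure. The share therefore rests on daf-2 replicate 3 and pfd-6 replicate 3, the libraries low in ribosomal protein transcripts. It was 0.98 without the stretch. With genes chosen at an unadjusted p under 0.001, the shares for replicates 1, 2 and 3 left out were 0.62, 0.507 and 0.904 (mean 0.677, SD 0.204, n = 3), and without the stretch 0.878, 0.917 and 1.035.

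**Figure D4:**
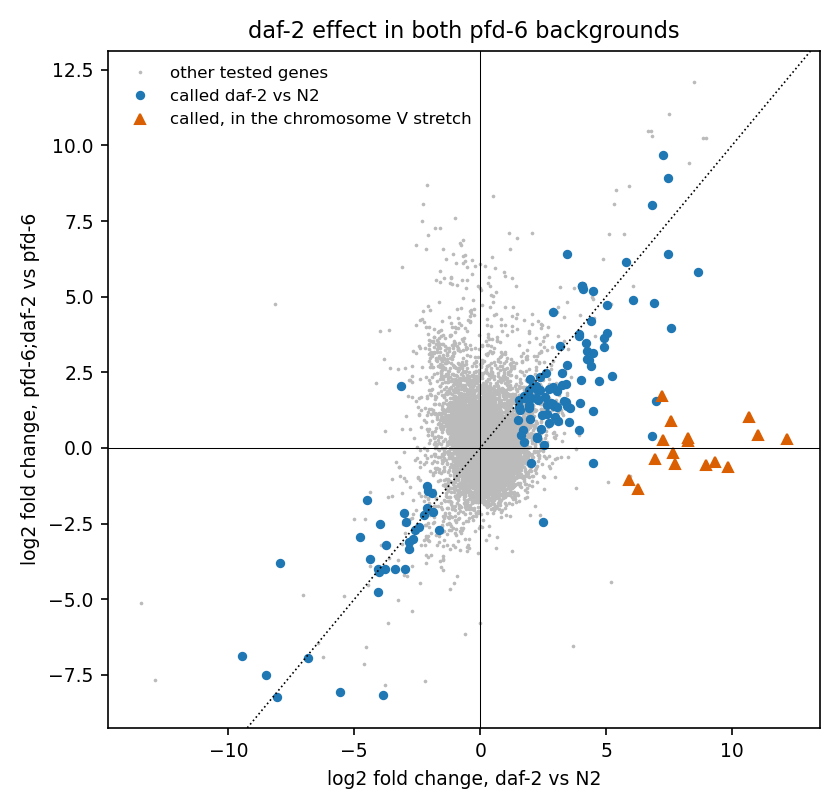
The log2 fold change of daf-2 over N2 (horizontal axis) and of the double mutant over pfd-6 (vertical axis) for 15090 genes. Of the 141 genes called daf-2 vs N2, blue points are those outside the chromosome V stretch and triangles those inside it. The dotted line marks equal change. Of the 125 called genes outside the stretch, 121 change the same way on both axes.

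Genes raised in daf-2 and lower again in the double mutant bear on which daf-2 responses depend on pfd-6, in part or in full. There were 7: hmt-1, H39E23.3, saeg-2, dmsr-16, F17E9.2, T23F11.6 and F40G12.5. The hmt-1 transcript averaged 14.5 ± 1.26 CPM in N2, 68.5 ± 17.4 in daf-2, 9.08 ± 4.29 in pfd-6 and 11.4 ± 1.88 in the double mutant, and dmsr-16 averaged 0.173 ± 0.109, 5.13 ± 1.82, 0.0821 ± 0.025 and 0.411 ± 0.206. Between the double mutant and pfd-6, hmt-1 did not pass the edgeR test (log2 fold change 0.33, adjusted p = 0.618). H39E23.3 still rose there, from 0.537 ± 0.533 to 29.2 ± 15.3 CPM (log2 fold change 5.80, adjusted p = 0.00292). Independent lists would share 0.415 genes, and the daf-2 libraries enter both comparisons with opposite signs. The covariance of the log2 fold changes across genes was -0.341, against -0.165 ± 0.0041 (SD of 20 simulations) for unchanged groups sharing those libraries. The correlation was -0.432, no stronger than the simulated -0.497, so part of the overlap may come from the shared libraries. Differences between replicate numbers, which hold no genotype effect and keep any pairing, gave correlations of -0.57, -0.709 and -0.758 for the same contrasts, with covariances of -0.041, -0.201 and -0.214 on the scale of the group means. In the mirror direction 4 genes were lowered in daf-2 and higher in the double mutant (0.901 for independent lists): clec-10, F55G11.2, ZK1010.5 and K08D10.14. From pfd-6 to the double mutant clec-10 still fell (log2 fold change -3.80, adjusted p = 0.00158), while ZK1010.5 went from 0.935 ± 0.553 to 3.93 ± 1.78 CPM. The 7 became 23 (mirror 7) with the replicate number as a block, 25 with DESeq2, 11 without daf-2 replicate 3 and pfd-6 replicate 3, and 12 without pfd-6 replicate 3. They became 3, 2 and 2 without N2 replicates 1, 2 and 3, 0, 1 and 0 without daf-2 replicates 1, 2 and 3, and 1, 2 and 0 without double mutant replicates 1, 2 and 3. Of the 7, F17E9.2 also passed the test of the interaction.

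The pfd-6 effects in the wild-type and daf-2 backgrounds share no libraries, but same-numbered libraries of pfd-6 and daf-2, and of N2 and the double mutant, vary together and enter with opposite signs. A negative correlation is therefore expected with no effect. Across genes, which are not independent replicates, the Spearman correlation of the effects was -0.294 (-0.158 with no filter on low counts, and -0.186 without daf-2 replicate 3), and -0.369 on group means of log2 CPM. Differences between replicate numbers, which hold no genotype effect, gave -0.544, -0.384 and -0.471 on the latter scale, so the correlation does not show opposed effects of pfd-6. None of the 14 genes higher in pfd-6 over N2 was among the 412 higher in the double mutant over daf-2 (0.382 for independent lists). Of these 14 genes, 13 lay in the chromosome V stretch, low in N2 alone, and N2 is not part of the second comparison. The overlap of 0 therefore says nothing about shared pfd-6 effects. The pfd-6 transcript was lower in both comparisons.

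The interaction asks whether the daf-2 effect differs between pfd-6 backgrounds. It was past the test for 21 genes, 4 higher and 17 lower, of which 13 lay in the chromosome V stretch, where N2 alone has almost no counts. The other 8 were col-38, clec-10, ZK1010.5, C02B10.6, clec-222, ins-19, F17E9.2 and D1086.3; ZK1010.5, C02B10.6 and ins-19 are outside the naming rule and were chosen after their values were seen. The collagen transcript col-38 averaged 4.59 ± 0.0624 CPM in N2, 2.04 ± 0.934 in daf-2, 0.776 ± 0.35 in pfd-6 and 13.5 ± 4.82 in the double mutant (interaction log2 fold change 5.29, SE 0.67, adjusted p = 0.0074). D1086.3 averaged 212 ± 34.6, 206 ± 58.6, 326 ± 71.1 and 51.7 ± 3.17 CPM. The raised class of DAF-16 targets had an interaction median of 0.08 (adjusted p = 0.117 at a preset correlation). Adjusted over each list alone, 77 collagens, 49 sperm genes and 4 pharynx genes were higher. With the genes of the stretch left out edgeR called 0 genes, in the full set 2627 genes had an unadjusted p under 0.05, and DESeq2 called 446. The count was 12 without N2 replicate 1, 12 without N2 replicate 2, 14 without N2 replicate 3, 13 without daf-2 replicate 3 and 12 without double mutant replicate 1, and 33 with a transcript length offset.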

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

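The tests of explanations weighed in this part, and the rules used to read them, were written down after the results were seen. The counts of called genes and lists in the real grouping were planned, except in settings named as added after the data were seen. The stretch on chromosome V was also delimited from the same data.

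The daf-2 effect differed between the pfd-6 backgrounds for 21 genes by the interaction test. The largest of them by the naming rule had interaction log2 fold changes of 5.29 (col-38), 4.14 (clec-10), -11.9 (lsy-27), -10.6 (fbxb-7), -4.95 (F17E9.2), -4.70 (clec-222) and -2.62 (D1086.3); those of lsy-27 and fbxb-7 rest on 0 counts in N2 and are no estimate of size. In 1 of 100 drawn splits of the 12 libraries, the real one, were as many genes called; the highest of the others gave 17. Those splits mix replicate numbers, which the libraries follow. Of the 32 splits that swap genotypes within numbers alone, 4 gave as many genes, the real one included, up to 126; with the replicate number as a block (36 genes) 5 did, up to 251. All the others as large keep the real grouping of daf-2 and the double mutant, which differ in 470 genes, so they are not free of effects and give no measure of arbitrary grouping. The 24 that mix those libraries gave at most 11 genes, and 0 outside the chromosome V stretch, where the real grouping gave 8. The 18 that mix both groupings gave 0 and are too few for a share under 0.05. Since the drawn splits ignore the numbers and those within numbers do not decide, arbitrary grouping is not excluded for the count. Of the 21 genes, 13 lie in the chromosome V stretch, and without the stretch 0 genes passed the edgeR test; 2627 had an unadjusted p under 0.05 and DESeq2 called 446 in the full set. Interaction medians of lists past the preset correlation test were 4.69 for sperm, 3.34 for cuticle collagens, 2.89 for pharynx, 1.59 for tubulin and actin, 1.28 for muscle, 1.07 for sugar and glyoxylate metabolism, 0.98 for ribosomal proteins, 0.96 for intestine, 0.65 for molting, 0.60 for germline and oocyte, 0.28 for proteasome and -0.73 for embryo. With an estimated correlation none of the 12 passed (lowest adjusted p = 0.599). Without daf-2 replicate 3 and pfd-6 replicate 3 the medians were -0.12 for ribosomal proteins, whose sign turned, 0.78 for tubulin and actin, 0.06 for proteasome and 3.82 for sperm. With replicates 1 and 2 alone they were -0.16, 0.60, -0.04 and 2.24, and 1.67 for collagens. Adjusted over the 26 lists of the comparison, as many as these 12 lists were called in 28 of the 100 splits, up to 17, so arbitrary grouping is not excluded for the number of lists.

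For each pairwise comparison 10 splits exist, too few for a share under 0.05. The real count of genes was 141 for daf-2 vs N2, 15 for pfd-6 vs N2, 470 for the double mutant vs daf-2 and 497 for the double mutant vs pfd-6, in 1 split each, and the highest other split gave 0 in all 4. Adjusted over the 26 lists of each comparison and not over all 130 tests, the numbers of lists called were 15, 15, 6 and 12 (8 in place of 6 over all 130), against highest others of 13, 15, 12 and 16; splits with as many numbered 1, 2, 10 and 3.

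The stretch of chromosome V held 20 consecutive genes under 1% of the expected N2 count. In 1000 random orders of the same 16131 genes the longest such run was 2, and the longest other run in the genome was also 2. Low depth is argued against by the 5563 N2 counts expected there, of which 9 were seen. A segment missing from these N2 animals is a candidate explanation, with 22 genes within 100 kb outside at a median of 81% of expected, 1 of them under 10%. Regulation by both mutations was not settled by the levels there. The median log2 ratio of pfd-6 over daf-2 levels was -0.45 (SD 0.92), and similar levels would be seen under either explanation.

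Replicate 3 of daf-2 and replicate 3 of pfd-6 were low in ribosomal protein transcripts. The genotypes are argued against, since the other libraries of both had at least 9.76% of counts from these genes. Transcript length is argued against as the whole cause, since the median deviation after its trend was removed was still -3.06 or lower (SD up to 1.45). A loss of abundant short transcripts may account for much of it: 68 other genes matched on abundance and length had median deviations of -2.67 and -3.54 (SD 1.69 and 2.22), against -3.78 and -5.44 for ribosomal proteins. The matched genes were less abundant, at a median log2 CPM of 9.69 against 10.42.

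Sperm and collagen transcripts were higher in the double mutant than in daf-2 (198 tested, 62 called, median 3.11, SD 1.92). A smooth trend with transcript length is argued against as the whole cause, with 72 called and a median of 3.08 (SD 1.91) after it was removed. Its removal left ribosomal proteins at a median deviation of -3.06 in daf-2 replicate 3. The offset therefore cannot decide on a loss of short transcripts beyond that trend. The libraries low in ribosomal proteins are argued against as the whole cause: without them the median was 2.82 (SD 1.90), though 11 were then called with fewer libraries in the test. Animals of another age or stage in the double mutant cultures cannot be told apart from the genotype, because ages within day 1 are not recorded. Of these genes 80.8% were highest in replicate 3 of the N2 libraries, against 39.8% of all tested genes, so they also vary among wild-type libraries. Whether cultures or sequencing sets differed there was not tested. The genotype remains an untested alternative.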

How the results depend on the processing

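The settings added after the data were seen were the transcript length offset with and without the replicate block, leaving out daf-2 replicate 3 and pfd-6 replicate 3, leaving out the chromosome V stretch, and choosing genes at an unadjusted p under 0.001. Counts of genes are given in the order daf-2 vs N2, pfd-6 vs N2, double mutant vs daf-2, double mutant vs pfd-6 and interaction, which were 141, 15, 470, 497 and 21. At an adjusted p under 0.01 they were 49, 9, 2, 64 and 10, and with DESeq2 401, 31, 916, 1290 and 446. The replicate block gave 253, 17, 814, 1496 and 36, and the block with the length offset 263, 17, 1112, 2489 and 89. The length offset alone gave 1137 for the double mutant vs pfd-6 and 33 for the interaction; it shifted the median of all genes to -0.19, -0.23 and -0.27 for the last 3. From the compared groups alone pfd-6 vs N2 gave 8 and the double mutant vs pfd-6 gave 248. Replicates 1 and 2 alone gave 9 for pfd-6 vs N2, 145 for the double mutant vs daf-2 and 6 for the interaction. Without daf-2 replicate 3 and pfd-6 replicate 3 there were 222 for daf-2 vs N2 and 163 for the double mutant vs daf-2. The same setting gave 586 for the double mutant vs pfd-6 and 17 for the interaction. No filter on low counts gave 38 for the interaction. Without the chromosome V stretch pfd-6 vs N2 and the interaction gave 0. Leaving out 1 of the 12 libraries in turn gave 41 to 249 for daf-2 vs N2, 9 to 16 for pfd-6 vs N2, 0 to 714 for the double mutant vs daf-2, 123 to 803 for the double mutant vs pfd-6 and 12 to 23 for the interaction. The cause of these changes was not tested.

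Of 62 list tests past the threshold at a preset correlation, 0 passed with an estimated correlation, and 60 passed with the replicate block. The 7 genes raised in daf-2 and lower in the double mutant became 25 with DESeq2, 23 with the replicate block, 11 without daf-2 replicate 3 and pfd-6 replicate 3, and 0 to 12 without 1 library. The correlation of the pfd-6 effects (-0.294) was -0.158 with no filter and -0.355 to -0.186 without 1 library. The share of the daf-2 response kept (0.863) rests on 1 measured replicate and has no SD of its own; other settings gave 0.677 to 0.98, with an SD of 0.204 among the 3 replicates at an unadjusted p under 0.001. Of 2381 values of called results of named genes, 1883 stayed past the threshold, 498 did not and 0 changed direction. The pairing check used deviations from the genotype means. Among libraries of other genotypes, each of the 12 libraries correlated best with a library of its own number, a hint from the data and not the design. Depth and spread limited calls of small changes: of simulated 2-fold changes 1.64% to 3.39% were called in the pairwise comparisons.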

Other observations

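The gene classes and genes in this part were chosen after their values were seen, and so was the chromosome test. Transcripts of nspc genes, a nematode-specific peptide family, were lower in both comparisons that add the daf-2 mutation. Of 18 tested members, 5 were called lower in daf-2 than N2 (Fisher's exact test, one-sided, adjusted p = 8.44e-08 over 1104 class tests) and 6 lower in the double mutant than pfd-6 (adjusted p = 3.37e-06); 17 of the 18 had a negative fold change in each. The nspc-18 transcript averaged 7.18 ± 3.14 CPM in N2, 0.526 ± 0.256 in daf-2, 3.33 ± 1.11 in pfd-6 and 0.202 ± 0.0508 in the double mutant (SD, n = 3). Of 22 tested pals genes, 3 were called higher in daf-2 than N2 (adjusted p = 0.0457, exact). Genes of 1 class can share reads, so class members are not independent.

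Between pfd-6 and N2 and between the double mutant and daf-2, 14 genes other than pfd-6 moved the same way, 12 higher and 2 lower. The limit was an unadjusted p under 0.01 in both comparisons. None of these genes passed the adjusted edgeR test between pfd-6 and N2. There scb-1 had adjusted p = 0.0936, hsr-9 adjusted p = 0.452 and fog-3 adjusted p = 0.572. Some lay near the floor, such as fis-1, which averaged 0.0109 CPM in N2 and 0.192 in pfd-6. Another 2 moved in opposite ways. Independent effects would give 6.11, but these effects correlate negatively in differences between replicate numbers, which hold no genotype effect. The 6.11 is therefore not the value for no change. Lower genes were scb-1, which averaged 23.9 ± 5.31 CPM in N2 and 7.82 ± 2.31 in pfd-6, and hsr-9, which averaged 425 ± 187 and 101 ± 46.7. The fog-3 transcript, from a gene needed for the sperm fate of germ cells, averaged 1.68 ± 0.602 in N2, 0.89 ± 0.0615 in daf-2, 4.79 ± 1.62 in pfd-6 and 11.4 ± 0.149 in the double mutant. Variants linked to pfd-6 on chromosome I were a hypothesis for the shared changes. Of the 14 genes, 5 lie on that chromosome (one-sided Fisher exact p = 0.0605). They lie between 5847477 and 10018121, a range that holds pfd-6, but nearness to pfd-6 was not tested. Linkage cannot be told apart from chance with this few genes.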
